A study of Caenorhabditis elegans with 2 samples.

How the data were processed

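Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was applied to whole young adult Caenorhabditis elegans carrying an integrated fosmid transgene of aptf-3, a gene of the AP-2 transcription factor family, fused to a TY1, EGFP and 3xFLAG tag. Per the labels' protocols, animals were synchronised from starved first-stage larvae and collected at 64 h, chromatin was sonicated to fragments of 200 to 800 bp, and the tagged protein was precipitated with an antibody to GFP. There was 1 group with 2 biological replicates, numbered as in the labels, and no second condition, so the comparisons are between replicates, between peak lists and between peaks and genomic backgrounds.

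The files were 8 peak lists. Each replicate had a ranked list and a thresholded list, and the series had a ranked and a thresholded list for each of an IDR set and a conservative IDR set. IDR, the irreproducible discovery rate, ranks peaks by how repeatable they are between lists. The deposited signal of each peak is the authors' own value on a scale that the sources used here do not define, and it was used to describe, rank and filter peaks, to correlate replicates across peaks and to compare peaks around aptf-3 and unc-119 with those of random windows in the same list. The deposited ranked lists also give the −log10 of the global IDR per peak. Tested on the files, every peak of the thresholded lists had an IDR of 0.01 or less in its ranked list. The reverse did not hold: 848 peaks of the ranked list behind the main list passed 0.01, and 63 of them were absent from the main list. The aligner, the peak caller and their versions are not given in the sources used here, and the control signal was not analysed here. The number of reads is not in the peak lists, so the depth of each replicate is unknown and no interval that needs it is given. In the series-level ranked lists, 16 columns hold values of single inputs that the labels do not tie to a replicate, and they were not used. Coordinates are those of ce11, with the Ensembl release 115 annotation of the same assembly. All peaks lay within its chromosome lengths. Positions are given 1-based.

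The IDR thresholded list of the series is called the main list. A promoter was 1000 bp upstream to 200 bp downstream of a gene's 5′ end. Shares of summits were compared with 10000 random placements of as many summits on the same chromosomes, drawn uniformly, so sequence that reads cannot be mapped to was included in this background. Feature classes were assigned by first match in the order promoter, 5′ UTR, coding exon, intron, 3′ UTR and intergenic. Peaks of the replicates were shared if they overlapped by at least 1 bp. Replicate signals were taken from each replicate's ranked list at the nearest summit within 100 bp, and correlated with 100000 permutations. Gene lists were tested with Fisher's exact test, two-sided, over 19973 nuclear protein-coding genes with 28 lists. Gene classes were tested in the same way over 46890 annotated genes, with 10 noncoding classes and the protein-coding genes. Odds ratios are sample values with 95% conditional intervals. The AP-2 consensus GCCNNNGGC was searched within 100 bp of each summit and in windows centred 500 bp to either side, with exact McNemar tests, and 5 permuted palindromes were searched in the same way. GC-matched backgrounds were 1000 draws of ranked-list peaks outside the main list, matched in bins of 4 bases. Windows of 40 kb around aptf-3 and unc-119 were compared with 10000 random windows. P values were adjusted by the Benjamini-Hochberg method within each family, with a threshold of 0.05. Intervals of shares are exact binomial 95% intervals over peaks and cover counting error only.

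Named genes were the nearest protein-coding gene of the 25 main-list peaks with the highest signal, every aptf gene, unc-119, flp-11 and, for each list past the threshold with more members than chance, the 4 members with the highest signal. Because 205 protein-coding genes share a symbol with another gene, genes were looked up by identifier. These rules, the gene lists, the tests and the first set of alternative settings were fixed before the data were examined. Alternatives were the conservative list, each replicate's own list, the upper 50% of peaks by signal, other windows, overlaps and matching distances, and other backgrounds. Merging overlapping peaks and leaving out summits near small RNA genes or soft-masked peaks were added after the data were seen.

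The gene list, motif, overlap and promoter tests were tested on simulated peaks, 20 runs each. A list with 30% of its members given a summit was called in 20 of 20 runs over 19973 genes, with 2 calls of other lists, and 0 of 560 tests were called with nothing planted. A motif written into the sequence at 20% of summits was found in 20 of 20 runs and in 0 without it. The planted shares exceeded those of the main list, at 4.08% of summits for the consensus and at most 12.5% of members in a called list. The simulated summits were uniform random positions. The runs therefore do not show the power for smaller effects, or how often the motif test passes at the GC content of real summits. Planted overlap of 40% was recovered as 40.1% on average. The promoter test passed 0.05 in 1 of 20 runs on random summits. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.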

Results

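Binding of the tagged AP-2 family factor APTF-3 was mapped in whole young adult worms at 64 h, in 2 biological replicates of 1 strain. The main list held 785 peaks and the conservative list 675, of which 541 had identical coordinates. Replicate 2 alone gave 241 thresholded peaks and replicate 1 alone 178. The main list covered 0.227% of the genome, with a median peak width of 296 bp and a median signal of 76.6 (range 2.13 to 322.3, in the authors' units). The depth of the libraries is unknown.

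The first question was how far the replicates gave the same sites. Of the 178 peaks of replicate 1, 93 overlapped a peak of replicate 2, or 52.2% (95% interval 44.6 to 59.8). Of the 241 peaks of replicate 2, 95 overlapped a peak of replicate 1, or 39.4% (33.2 to 45.9). Random placement gave means of 0.136% and 0.1%, and a one-sided permutation p of 0.0001 for both, the smallest that 10000 placements can give. In the main list, 94 peaks overlapped both replicate lists and 493 overlapped neither. Across the 701 main-list peaks matched in both replicates, the replicates' signals had a Spearman rho of 0.21 and a Pearson r of 0.336 on the log10 scale, each with a permutation p of 2e-05, two-sided, the smallest that 100000 permutations can give. Without the 2 peaks farthest from the median of replicate 1, r was 0.37. In the conservative list, with 592 matched peaks, rho was 0.324 and r 0.575. Peaks are not independent replicates, and these peaks had been selected for passing a joint threshold.

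**Figure D1:**
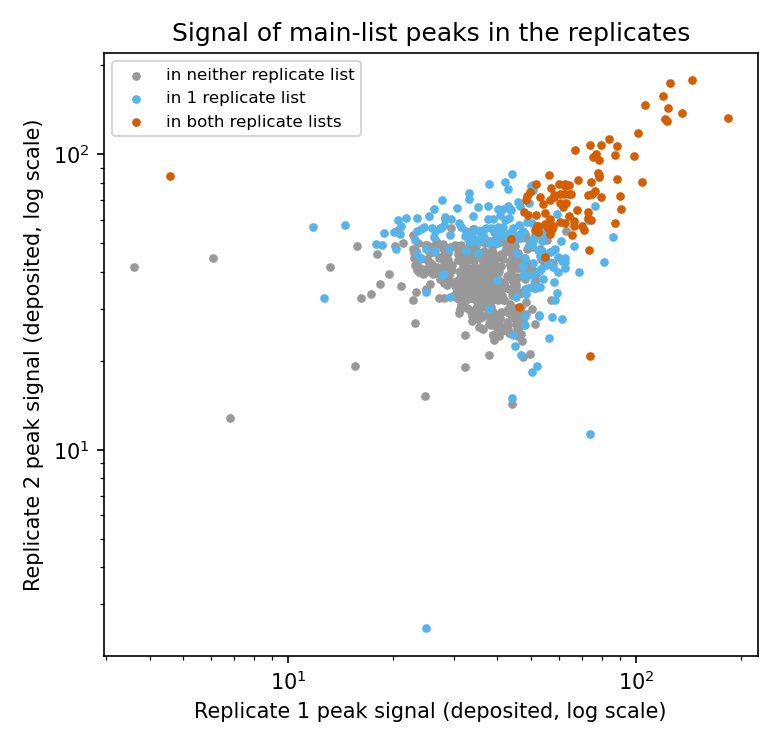
Deposited signal of the 701 main-list peaks matched in both replicates, replicate 1 on the x axis and replicate 2 on the y axis, both on log scales. Each point is a peak, coloured by whether it overlaps the thresholded list of neither, 1 or both replicates; peaks in both lists lie at the upper right.

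The 25 strongest peaks of the main list, with signals from 165 to 322.3, were all in both replicate lists. With the 63 ranked peaks past the IDR threshold but absent from the main list counted too, 11 of the 25 highest were absent ones. The strongest of the main list lay on chromosome I at 7868978 to 7869257, in an annotated 5′ UTR of pck-2, a phosphoenolpyruvate carboxykinase gene. The nearest protein-coding 5′ end was that of R11A5.6, 1190 bp away. The third, on chromosome II at 11759410 to 11759495 with a signal of 297, was 172 bp upstream of F44E5.4, a gene of the hsp-70 family. The peak at mrp-4, an ABC transporter gene, on chromosome X at 9883944 to 9884080 had a signal of 217 and lay 273 bp from its 5′ end. The peak at mdt-26, a Mediator subunit gene, on chromosome II at 5661687 to 5661815 had a signal of 251 and lay in an intron. The peak at eel-1, a ubiquitin ligase gene, on chromosome IV at 3050442 to 3050515 had a signal of 166. Of the 25 summits, 14 lay in a promoter of some annotated gene, 7 were intergenic, 3 intronic and 1 in a 5′ UTR, and 17 were over 1000 bp from any protein-coding 5′ end. Near the latter the nearest genes included ccm-2, fbxa-190, pxn-1, str-56, nlp-76 and cutl-18, at 1364 to 5664 bp. The summits assigned to pxn-1, str-56 and cutl-18 lay 26, 37 and 33 bp from the 5′ end of a snoRNA gene. That assigned to nlp-76 lay 39 bp from the 5′ end of a tRNA gene, and that assigned to ccm-2 in an intron of cmk-1. Of all 25 summits, 6 lay within 100 bp of a tRNA or snoRNA gene, and the summit in ints-8 was 29 bp from the 5′ end of rpr-1, the RNase P RNA gene. At least 50% of the bases were soft-masked, the annotation of repeats, in 8 of the 25 peaks. These include the strongest peak, in pck-2, and the peak assigned to fbxa-190, at 100% each, and the eel-1 peak at 50%. The peaks at F44E5.4, mrp-4 and mdt-26 had 0%.

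The second question was where the peaks lay. No control signal and no other factor were compared here. Peaks particular to APTF-3 could therefore not be told apart from sites shared by many factors. Promoters of any annotated gene held 474 of 785 summits, or 60.4% (56.9 to 63.8), against 33.9% of random positions (two-sided permutation p = 0.0002, the smallest possible). For protein-coding genes alone the share was 32.6% (29.3 to 36.0) against 21.4%, with the same p. Introns held 9.81% of summits against 26.6% at random and coding exons 10.7% against 18.03%, both lower with an adjusted p of 0.0004. The coding exon share was lower still in the replicates' own, shorter lists, at 3.93% in replicate 1 and 4.15% in replicate 2, or 14.2 and 13.7 points below random against 7.33 in the main list. Intergenic positions held 15.3% against 18.6% (permutation, adjusted p = 0.0243), a difference of -3.31 percentage points. In the shorter lists of replicate 1 and replicate 2 it was -2.99 and -4.14 points and did not pass the permutation test (adjusted p = 0.414 and 0.167), while in the conservative list it was -6.19 points (12.4% against 18.6%, permutation, adjusted p = 0.0003). The 5′ UTR share (0.764% against 0.71%, adjusted p = 0.973) and the 3′ UTR share (3.06% against 2.1%, adjusted p = 0.103) did not differ past the threshold of the permutation test. No chromosome differed from its share of genome length after adjustment in exact binomial tests: the largest excess was 132 peaks against 107.9 expected on chromosome III (unadjusted p = 0.0147, adjusted p = 0.0885), the only chromosome of 6 with an unadjusted p under 0.05.

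**Figure D2:**
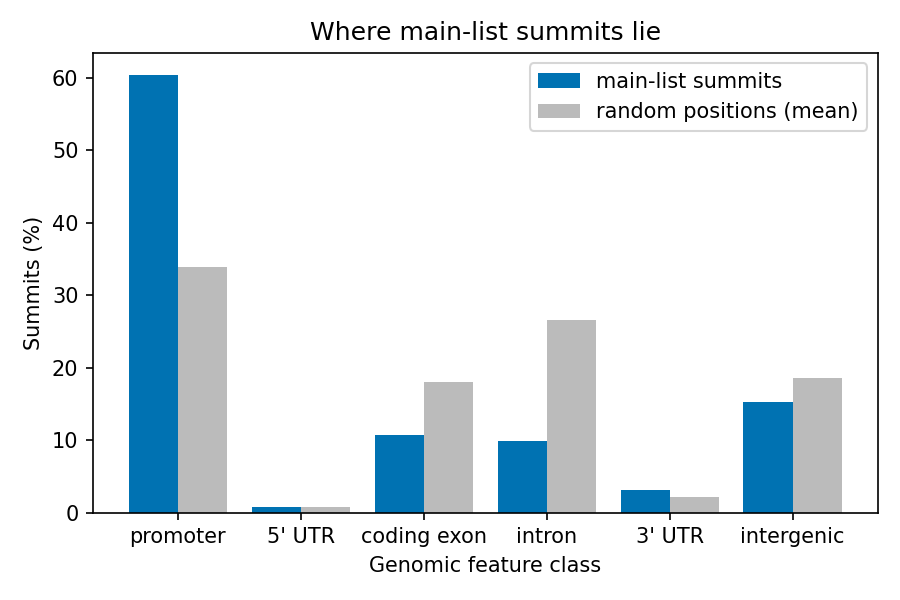
Share of the 785 main-list summits (blue) and mean share of random positions (grey) in each feature class, in percent of summits. Promoters hold 60.4% of summits against 33.9% at random, and introns 9.81% against 26.6%.

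Genes for small structural RNAs stood out among gene classes. A main-list summit lay in the promoter window of 156 of 612 tRNA genes (25.5%, against 1.42% of other genes; odds ratio 23.8, 95% interval 19.4 to 29.0), 25 of 129 snRNA genes (19.4%; odds ratio 14.02, 8.63 to 22.01) and 53 of 346 snoRNA genes (15.3%; odds ratio 10.9, 7.9 to 14.8). Their adjusted p values by Fisher's exact test were 1.48e-134, 1.03e-18 and 3.63e-33. The tRNA genes shared 127 distinct summits, so genes are not independent. The order of the classes differed between the replicates' own, shorter lists: in that of replicate 1 the odds ratio was 13.97 for tRNA genes (5.39% with a summit) and 20.2 for snoRNA genes, and in that of replicate 2 it was 20.9 for tRNA genes (9.97%) and 12.9 for snoRNA genes. Other noncoding RNA genes had an odds ratio of 1.91 (2.85% against 1.51%, exact-test adjusted p = 3.29e-14). For every class but piRNA, the comparison genes include the 15363 piRNA genes, few of which had a summit. This raises the odds ratios above those against the remaining genes alone, which were not calculated. Peaks were fewer than at other genes at piRNA genes (28 of 15363, odds ratio 0.0715, exact-test adjusted p = 4.06e-98), which lie in dense clusters; in the list of replicate 1 the count was 1 (odds ratio 0.00926). This was not particular to the main list: 0.382% of its summits lay within 100 bp of a piRNA gene, against 0.311% of the other ranked peaks and 1.98% of random positions. Pseudogenes also had fewer (odds ratio 0.608, exact-test adjusted p = 0.0266), a difference lost in the list of replicate 1 (adjusted p = 1.0). Against this background, protein-coding genes had an odds ratio of 0.776 (exact-test adjusted p = 0.000947), a direction that depended on the window: with a summit in or within 100 bp of the gene the log2 odds ratio was 0.51, an excess past the threshold (odds ratio 1.42, exact-test adjusted p = 1.19e-06), and with 2000 bp upstream to 500 bp downstream it was 0.0116. The call was also lost in the list of replicate 1 (log2 odds ratio -0.30, exact-test adjusted p = 0.246). At miRNA, lincRNA, antisense RNA and rRNA genes the differences did not pass the threshold in the main window (exact-test adjusted p of 0.313 or more). The miRNA genes passed with 500 bp upstream to 100 bp downstream (odds ratio 2.33, exact-test adjusted p = 0.0498) and with 2000 bp upstream to 500 bp downstream (1.98, 0.0434).

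Of 19973 protein-coding genes, 298 had a main-list summit in the promoter window, and 5 of 28 gene lists differed from the other genes. The 298 genes shared 256 distinct summits. A summit counted for a listed gene can thus also count for a neighbour outside the list. Examples are rps-1 with ifet-1, hsp-110 with rpn-3, and lin-35 with vps-51. Cytoplasmic ribosomal protein genes had 10 of 80 members with a summit (12.5% against 1.45%; odds ratio 9.72, 4.42 to 19.2; exact-test adjusted p = 8.63e-06), led by rpl-3 with a signal of 151, rpl-35 with 149, rpl-15 with 92.6 and rps-1 with 89.3. The rpl-3 peak spanned 3867410 to 3867705 and the rpl-35 peak 7854553 to 7854848, both on chromosome III. The rpl-3 peak had signals of 79.2 in replicate 1 and 71.5 in replicate 2. The rpl-35 peak had 76.1 in replicate 2 and no matched signal in replicate 1. Heat shock protein genes had 5 of 52 (odds ratio 7.13, 2.2 to 18.02; exact-test adjusted p = 0.00977): dnj-13, a DnaJ cochaperone gene, had a signal of 114, the ER chaperone gene hsp-3 80.7, the mitochondrial chaperonin gene hsp-60 73.2 and hsp-110 70.4. This list was set by gene symbol before the data were seen and does not hold F44E5.4 or its neighbour F44E5.5, which share the peak with a signal of 297. Cell cycle and mitosis genes had 5 of 72 (odds ratio 4.99, 1.56 to 12.4; exact-test adjusted p = 0.0263): cdc-25.3, a CDC25 phosphatase gene, had a signal of 109, cdc-48.1 86.9, the retinoblastoma family gene lin-35 82.4 and the kinetochore gene knl-3 75.6. Core histone genes had 5 of 73 (odds ratio 4.92, 1.54 to 12.2; exact-test adjusted p = 0.0263) from 4 distinct summits, at his-58 (WBGene00001940, signal 86.9), his-61 (82.5), his-42 (74.9) and his-63 (69.3). Chemoreceptor genes had fewer, 4 of 1365 (0.293% against 1.58%; odds ratio 0.183, 0.0495 to 0.475; exact-test adjusted p = 0.000187). Only 1 of 176 cuticle collagen genes (exact-test adjusted p = 0.923) and 0 of 14 epidermal regulators (adjusted p = 1.0) had a summit. The list of replicate 2 gave 1 call, the ribosomal protein genes, and that of replicate 1 gave 0 by Fisher's exact test, with 5 lists at an unadjusted p under 0.05. The odds ratios in the lists of replicates 1 and 2 were 9.8 and 8.35 for heat shock proteins (2 members each) and 0.166 and 0.141 for chemoreceptors (1 each), all farther from 1 than in the main list, while that of the ribosomal protein genes was 6.27 in replicate 1 (2 of 80) and 14.3 in replicate 2 (5 of 80). The cell cycle call was lost in the conservative list (exact-test adjusted p = 0.51), where the respiratory chain genes were called with 4 of 41 members (odds ratio 7.84, adjusted p = 0.0134). In the upper 50% of peaks the heat shock call (2 members, odds ratio 4.65, exact-test adjusted p = 0.345) and the cell cycle call (3 members, odds ratio 5.08, adjusted p = 0.17) were lost. The core histone call was lost with a window of 500 bp upstream to 100 bp downstream (2 members, odds ratio 3.05, exact-test adjusted p = 0.509). It was also lost with the nearest gene only (4 members, log2 odds ratio 1.82, exact-test adjusted p = 0.109). In the upper 50% of peaks it was lost with 2 members (odds ratio 3.27, exact-test adjusted p = 0.457). The conservative list gave 8 of 73 (odds ratio 9.05, exact-test adjusted p = 6.75e-05).

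**Figure D3:**
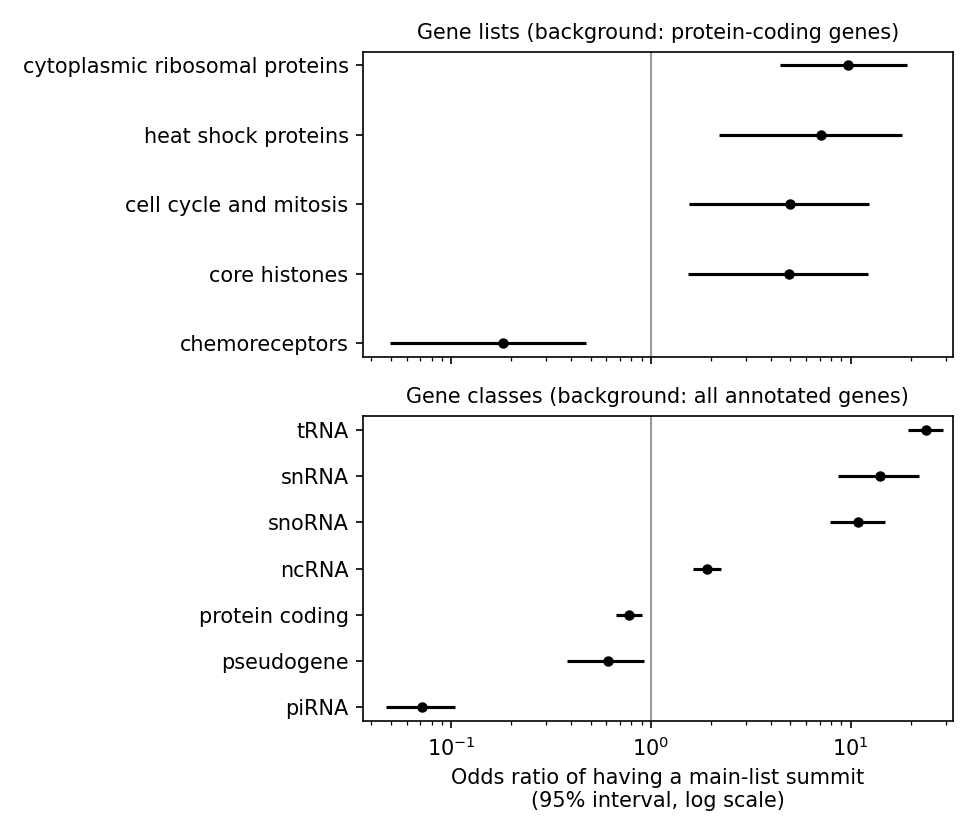
Odds ratios (points) with 95% intervals (bars) on a log scale for gene lists (top) and gene classes (bottom) past an adjusted p of 0.05 in the main list; the vertical line marks an odds ratio of 1. The tRNA genes, at 23.8, lie farthest to the right.

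The third question was whether summits carried the AP-2 consensus. GCCNNNGGC occurred within 100 bp of 32 of 785 summits, or 4.08% (2.8 to 5.71), against 1.15% in the left and 1.53% in the right flanking windows (exact McNemar p = 0.000294 and 0.00289, two-sided). Of the 5 permuted palindromes 4 were also more frequent at summits, with GGCNNNGCC at 6.37% against 1.78% and 2.29% in the flanks and GCGNNNCGC at 5.61%. The exception was CGGNNNCCG, at 3.31% against 2.55% in both flanks (exact McNemar p = 0.418 and 0.43). Mean GC content was 46.2% at main-list summits (SD 7.21 over peaks) and 40.2% (SD 6.54) at other ranked peaks. GC-matched peaks carried the consensus at 3.01% (95% of draws between 1.91 and 4.2), a difference from the main list that did not pass the threshold (two-sided p = 0.122 from a permutation test over the draws). With spacings of 2 to 4 bases allowed between the arms, 10.2% of summits carried a match against 3.82% and 4.59% in the flanks. The share of the consensus was 3.32% in the list of replicate 2 and 1.69%, below its flanks, in that of replicate 1. The consensus did not follow signal rank (rho -0.04, permutation p = 0.315): it occurred at 2.03% of the 197 strongest summits and at 5.1%, 4.59% and 4.59% in the following groups of 196, and at 0 of the 25 strongest.

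The tagged gene itself and its relatives had no main-list summit in their promoter windows: aptf-1, aptf-2, aptf-3 and aptf-4 had 0 of 4, as did unc-119, the rescue marker of the transgene, and flp-11, a neuropeptide gene known to act downstream of APTF-1. The 40 kb around aptf-3, on chromosome II from 8575240 to 8615240, held 4 main-list peaks against a mean of 0.309 in random windows, of which 0.35% held as many (one-sided permutation p = 0.0036). The peaks lay in puf-5, 752 bp upstream of F54C9.9 (signal 82.3), at arl-1 (54.4), in F54C9.11 (67.8) and upstream of suf-1 (64.0). Those in puf-5 and at arl-1 had no replicate 1 summit matched within 100 bp. The arl-1 peak overlapped neither replicate's thresholded list. The 40 kb window held 2 peaks in the conservative list (permutation p = 0.046) and 2 in the list of each replicate (0.0055 for replicate 1 and 0.0093 for replicate 2). A 20 kb window held 1 main-list peak (permutation p = 0.126). Around unc-119 there were 0 main-list peaks.

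**Figure D4:**
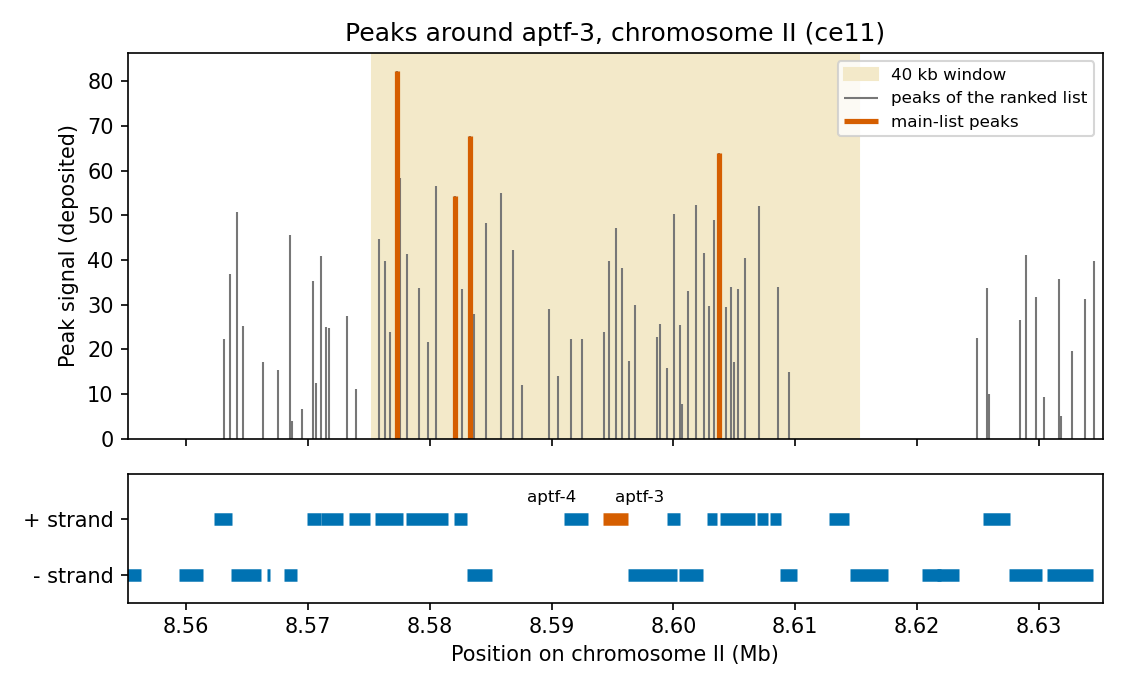
Position on chromosome II in Mb (x axis) against deposited peak signal (y axis) around aptf-3, with peaks of the ranked list in grey, the 4 main-list peaks in orange and protein-coding genes by strand underneath. The shaded 40 kb window holds all 4 main-list peaks of the region shown.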

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

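The tests of explanations for the aptf-3 region, by gene density and by signal outside promoters, were chosen after its strongest peaks had been seen. No biological explanation was tested for these patterns, since the design has 1 group.

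Strong peaks absent from the main list were seen in the ranked list behind it. Of 848 ranked peaks with an IDR of 0.01 or less, 63 were absent, and the strongest of these, on chromosome X at 15810961 to 15811256, had a signal of 1526, 4.73 times the main-list maximum of 322.3. The absent peaks had 71.9% of their bases soft-masked on average (SD 38.1) and the main-list peaks 24.5% (SD 24.1), a difference of 47.4 percentage points (95% bootstrap interval 37.6 to 56.7, permutation p = 2e-05, two-sided). Repeated or multi-copy sequence is therefore a candidate explanation for most of the absent peaks, but 8 of the 63 had no soft-masked base, and the rule that removed them is not given in the sources used here. Some absent peaks overlapped or lay close together, also among the 8. They are not independent, so the interval and the permutation p are likely too narrow and too small.

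Main-list peaks crowded around aptf-3. For the count of main-list peaks, a gene-dense region was argued against. Among 491 random windows with at least as many protein-coding 5′ ends, the count of 4 lay at the 99.4th percentile. This count includes peaks without a matched replicate 1 summit. The comparison was not run for the conservative list or the replicates' own lists. Extra copies of transgene DNA stay open as a candidate explanation. The 26 ranked-list peaks outside promoters in the 40 kb window had a median signal of 33.6, at the 99.5th percentile of random windows. The window at unc-119 was at the 48.2nd. These random windows were not matched for gene density. The aptf-3 window held 15 protein-coding 5′ ends, against a mean of 7.98 in random windows. The percentile therefore cannot separate extra copies from a gene-dense region. The extents of the fosmid insert and of the unc-119 marker were not established here. Extra copies of a marker much shorter than 40 kb could leave the median of the unc-119 window unchanged. The rise at aptf-3 was uneven. With promoter peaks included, the median signal in the 4 bins of 10 kb was 43.1, 23.9, 29.9 and 33.9 from left to right. In bins outside the window, up to 100 kb from its centre, the medians ranged from 13.6 to 31.3. Both extremes lay to the right, at 40 to 50 kb and at 30 to 40 kb. The bins of the window at 23.9 and 29.9 lay within that range, and those at 43.1 and 33.9 lay above it. The 47 ranked-list peaks of the window were not unusually many, at the 61.1st percentile (one-sided permutation p = 0.389). Input signal over the region, which would show copy number directly, was not analysed here.

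The AP-2 consensus was more frequent at summits than in flanks. GC content may account for this: the share exceeded the mean of GC-matched peaks by 1.07 percentage points, within the spread of the draws, and 4 of the 5 permuted palindromes were raised past an exact McNemar p of 0.05 on both sides as well. A smaller excess of the consensus cannot be excluded with 32 occurrences.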

How the results depend on the processing

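Merging overlapping peaks, leaving out summits near small RNA genes or soft-masked peaks, and counting summits in or within 100 bp of a gene were chosen after the data were seen. Replicate overlap, signal agreement, promoter share, the count of feature classes, the chromosome distribution and the motif's lack of relation to rank kept their direction and side of the threshold, or a count within 1.5 times, under every alternative run for them. For replicate overlap this carries little weight. A share cannot turn negative, and uniform random placement gave a mean of 0.136% or less in each setting. The promoter excess was 26.5 percentage points and ranged from 33.3 to 35.5 in the replicate lists. Peak counts ranged from 178 to 241 with a single replicate. The number of gene lists past the threshold fell from 5 to 2 in the upper 50% of peaks and to between 0 and 1 with a single replicate; these lists hold fewer peaks. A tally was made over all results and settings. It took in single gene lists and gene classes only if they had members with a main-list summit and were called in some setting. In it, 165 values kept their direction and side of the threshold or a count within 1.5 times. These include values that passed in neither setting and the counts of 0 at unc-119. Another 24 kept their direction but no longer passed, and 5 newly passed. A further 5 counts moved by more than 1.5 times and 6 values changed sign. The 5 new calls were the respiratory chain genes in the conservative list and with the nearest gene only, the germline and oocyte genes with the 2000 bp window, and the miRNA genes with both other windows. The nuclear hormone receptors, with 0 members in the main list and so outside the tally, were called as fewer with the 2000 bp window (1 of 274). The AP-2 excess of 2.74 points over flanks was 1.91 in the upper 50% of peaks, 1.08 within 50 bp and 1.07 against GC-matched peaks, none past the threshold, and from -0.843 to 1.66 with a single replicate; the cause was not tested beyond GC content. It stayed past the threshold at 5.99 with spacings of 2 to 4 bases, 2.89 in the conservative list, 2.61 within 150 bp, 2.93 with overlapping peaks merged and 3.06 without summits near small RNA genes. The count at aptf-3 was 1 in a 20 kb window and 2, still past the threshold, in the conservative list and in each replicate's list. The 3′ UTR difference of 0.961 points, not past the threshold, ranged from -0.408 to 0.387 with a single replicate. The log2 odds ratio of miRNA genes ranged from -0.77 to 0.71 with a single replicate and was -0.21 with summits in or within 100 bp of the gene, against 0.65 in the main window; the cause was not tested. The log2 odds ratio of protein-coding genes was -0.36 and turned to 0.0116 with the 2000 bp window and to 0.51, past the threshold, with summits in or within 100 bp of the gene; the windows cover different sequence. Core histone genes had 0 members with a summit in the list of replicate 1, which gives no log2 odds ratio. The depth of the libraries is unknown, so its effect on the replicate lists could not be assessed.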

Other observations

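These values were chosen after the data were seen. In the main list, 197 summits (25.1%) lay within 100 bp of a tRNA, snoRNA, snRNA or rRNA gene, against 0.565% of the other ranked peaks. By class, 124 summits were near tRNA genes (15.8%, against 0.16% of random positions), 47 near snoRNA genes (5.99% against 0.117%) and 26 near snRNA genes (3.31% against 0.0396%), each with an adjusted one-sided permutation p of 0.00025, and 0 near rRNA genes. Genes annotated as ncRNA without a further class had 161 summits nearby (20.5%, against 2.28% of random positions and 3.33% of the other ranked peaks, same adjusted permutation p). Smaller excesses over random were seen near miRNA genes (4 summits, 0.51% against 0.0709%, adjusted permutation p = 0.005) and lincRNA genes (5, 0.637% against 0.28%, adjusted permutation p = 0.039). Against other genes at the same distance, the odds ratios were 0.865 for miRNA and 1.47 for lincRNA genes. Neither passed the threshold of the exact test. For the genes annotated as ncRNA the odds ratio was 1.29 (2.16% against 1.69% of other genes, exact-test adjusted p = 0.00723). The shares near pseudogenes (18 summits, 2.29% against 3.5%) and piRNA genes (3, 0.382% against 1.98%) did not exceed random. The ribosomal protein genes had a log2 odds ratio of 3.43 without these summits and 3.28 with them, and core histone genes 2.27 without and 2.30 with them, with 4 members instead of 5 and an exact-test adjusted p of 0.0649. Genes of the respiratory chain had 3 of 41 members with a summit (cox-6A with a signal of 128, cox-5B with 122 and cyc-2.1 with 72.1) and splicing factors 3 of 45, with exact-test adjusted p values of 0.108 and 0.118 that did not pass the threshold in the main list. The respiratory chain genes passed in the conservative list and when only the nearest gene was counted (exact-test adjusted p = 0.0134 and 0.0243). The summit at cyc-2.1 also counted for rpl-20.

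A set of 29 main-list peaks had a signal under 20, far below the list's median of 76.6. None of the 29 had a summit matched in both replicates' ranked lists within 100 bp, against 701 of the other 756 peaks, and 8 overlapped a thresholded peak of either replicate.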
